A study of Rattus norvegicus with 6 samples.

How the data were processed

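RNA was measured in 6 tissues of male Brown Norway rats aged 6 weeks, with 1 sample per tissue. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded RNA LT kit. Per the submitters' processing notes, the genome build was rn5 and bcl2fastq 2.15.0 was used. The deposited table gave FPKM (fragments scaled by transcript length and by the total of the library) for transcripts that the authors had selected as lncRNAs. The aligner, the program that estimated FPKM, its annotation, the strand setting and the criteria for a lncRNA are not given in the sources used here. The column names are those of a Cufflinks tracking file, per the file headers. Its class codes relate each transcript to a reference gene, as a match, a shared splice junction, another overlap or an exon on the opposite strand. The length of each transcript in bases was a further deposited value, of another kind than FPKM. Coordinates are those of the locus on rn5 as the table gives them, and whether starts count from 0 or 1 is not stated. Several loci can be listed with the same interval. The table of reference genes at hand was of another assembly, matched 0 of the identifiers and was not used.

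Each tissue had 2 FPKM columns, with codes that begin with 1 or 2. The letters of 5 codes each fitted 1 tissue label. The remaining code, B, was matched to hypothalamus by elimination, so each statement on hypothalamus rests on that match. Of 2458 transcripts, 3 without values were left out. The design fixed before the data were examined assumed 1 library per tissue and stated that, with more columns, they would be averaged for counts and tested with limma in place of a rule of size. No counts were given, so no count test was run. The low values of transcripts over 500 bases that were alone at their locus fell on steps, which gave the FPKM of 1 fragment per kb with an assumed mean fragment of 140 bases. Between 86.7 and 93.2% of these values lay within 0.15 of a whole number of fragments. The implied depths of columns 1 and 2 were 12090000 and 3873000 fragments in liver, 17260000 and 14860000 in cortex, 17470000 and 18380000 in outer medulla, 10240000 and 10130000 in left ventricle, 13480000 and 17520000 in adrenal gland, and 27490000 and 31840000 in hypothalamus. Low values in liver column 2 are therefore the least precise.

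Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, R 4.3.3 and limma 3.58.1. A transcript was detected at a mean FPKM of 0.5 or more. limma with a mean-variance trend was run on log2(FPKM + 0.1) over the 12 columns with tissue as the factor, for transcripts at a mean FPKM of 1 or more in at least 1 tissue. Fold changes are on that scale. The added 0.1 shrinks changes of low transcripts, but a fold over a listed 0 that hides a value above 0.1 can be too large. A transcript was restricted when its highest tissue exceeded each of the other 5, taking the largest p and adjusting it with the Benjamini-Hochberg method at 0.05. Tau was computed on log2(FPKM + 1). Lists of marker genes were compared with 10000 random lists of the same size, matched on mean expression, where at least 3 transcripts were found. Neighbouring loci were compared with 10000 shuffles.

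Named transcripts followed a rule fixed in advance. It took per tissue the 3 with the highest FPKM and the 4 restricted ones with the largest ratio to the next tissue. It also took the 5 largest differences in each direction between outer medulla and cortex, the 4 with the lowest tau at FPKM 1 or more in all tissues, and all members found of the list of known lncRNAs. The tests were checked on simulated data. For outer medulla against cortex (482 transcripts), 43.9% of 2-fold, 62.7% of 4-fold and 79.1% of 8-fold changes were recovered, and 12 of 136 calls (8.8%) were false. For tissue-restricted transcripts (1269), 3.0% of 2-fold, 31.3% of 4-fold and 56.7% of 8-fold changes were recovered, with 0 of 61 calls false. In that simulation the unchanged transcripts were equal in all tissues, so few false calls could arise. Transcripts high in several tissues were not simulated. Each simulated transcript also had the same spread in every tissue, while the real liver columns stood further apart than those of other tissues.

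The alternatives were other FPKM minimums, pseudocounts of 0.01 and 1, rescaling of tissues, a 10-fold rule of size, other forms of tau, outer medulla and cortex averaged, and each column left out in turn. Further alternatives were chosen after seeing the data: rescaling of columns, sums per locus, 5-fold and 4-fold rules of size, a block for the column number, the spread of outer medulla and cortex columns alone, no hypothalamus columns, subtraction of the share of the other tissue in adrenal gland and hypothalamus, and both of adrenal gland column 2 and hypothalamus column 1 left out. The 5-fold and 4-fold thresholds were fixed in advance for the case of 1 library per tissue. Only their use beside limma was chosen later.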

Results

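Long non-coding RNAs (lncRNAs) were profiled by RNA sequencing in 6 tissues of male Brown Norway rats aged 6 weeks, an inbred strain. The tissues were liver, cortex, outer medulla (a region of the kidney), left ventricle of the heart, adrenal gland and hypothalamus, with 1 sample per tissue. The label of the cortex sample names no organ. The deposited table gave 2 FPKM columns for each tissue, called column 1 and column 2 here. Where 2 values are printed for a transcript in a tissue, they are in that order. The labels do not say whether the 2 columns of a tissue came from separate animals, so p-values measure only the spread between columns, which may be technical. For each transcript this spread was pooled over all 6 tissues, so a p also reflects tissues that are not being compared. The table held 2455 transcripts with values at 1646 loci. Of these, 1722 had no reference gene and 733 were assigned to one, among them 189 that lay antisense to an exon of it. Whether reads were counted by strand is not given in the sources used here, so values of transcripts that overlap or lie antisense to a gene may include reads of that gene. The median transcript length was 1758 bases. The steps between low FPKM values implied from 3873000 fragments in liver column 2 to 31840000 in hypothalamus column 2. With 3 fragments taken as the limit of a count of 0, a transcript with 1 kb of usable length could therefore reach an FPKM of 0.775 in liver column 2 and 0.0942 in hypothalamus column 2 and still be read as 0. These limits cover counting error only, and an exact 0 in a table without counts can also be a failed estimate.

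The order of the tissues by number of detected lncRNA transcripts depended on the setting. At a mean FPKM of 0.5 or more, as deposited, 799 transcripts were detected in cortex, 764 in outer medulla, 685 in liver, 653 in adrenal gland, 612 in left ventricle and 494 in hypothalamus. When the tissues were rescaled to the same median over transcripts above 0 in all of them, the counts were 762 in hypothalamus, 718 in liver, 697 in cortex, 651 in adrenal gland, 640 in left ventricle and 608 in outer medulla. At an FPKM of 1 liver had 473 and cortex 472, and above 0 liver had the fewest (1731). In total 1812 transcripts were detected in at least 1 tissue. Of those, 899 (49.6%) were detected in exactly 1 tissue and 142 (7.8%) in all 6 tissues.

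**Figure D1:**
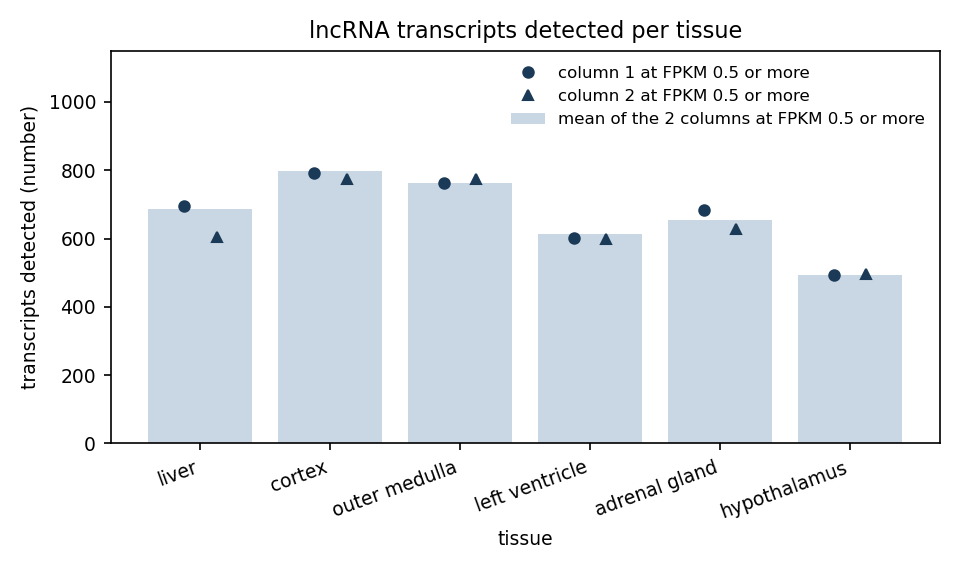
Number of transcripts at an FPKM of 0.5 or more (vertical axis) in each of the 6 tissues (horizontal axis); bars show the count on the mean of the 2 columns and points the count in each column. Counts on the mean run from 494 in hypothalamus to 799 in cortex, and in liver column 1 had 696 and column 2 had 605.

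A few transcripts took much of the measured abundance. The 10 most abundant transcripts held 69.1% of the total FPKM in hypothalamus, 64.5% in cortex, 63.0% in adrenal gland, 59.5% in left ventricle, 58.2% in liver and 47.0% in outer medulla. Without the most abundant transcript of each tissue, the next 10 held 53.98, 49.15, 51.99, 44.36, 52.47 and 28.94% of the remaining FPKM, in the same order. TCONS_00012467, a transcript of 11142 bases with no reference gene (rn5 chromosome 1, 228080092 to 228091758), was among the 3 most abundant in 5 tissues. Its FPKM was 850.5 and 774 in cortex, 833 and 837 in outer medulla, 1112 and 953 in left ventricle, 1231 and 916 in adrenal gland, and 352 and 279 in hypothalamus. TCONS_00012465, from the same locus, reached 186 and 212 in outer medulla. TCONS_00015674, which overlaps ENSRNOG00000047167 (chromosome 10, 58888597 to 58890286), was among the top 3 in all 6 tissues, at 1587 and 555 in liver and 153 and 148 in outer medulla. TCONS_00032703, which overlaps ENSRNOG00000049138 (chromosome 14, 46814997 to 46864150), had 1256 and 1302 in adrenal gland and 891 and 1335 in hypothalamus. In cortex it had 3416 in column 1 and was listed at 0 in column 2, and it was listed at 0 in both columns of the other 3 tissues. The share of the 10 most abundant transcripts in cortex was 73.6% in column 1 and 48.0% in column 2.

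Whether a lncRNA marked a single tissue was tested with limma on log2(FPKM + 0.1), comparing the highest tissue of each transcript with each of the other 5. Of 1269 transcripts with a mean FPKM of 1 or more in at least 1 tissue, 580 (45.7%) were higher in 1 tissue than in every other at a Benjamini-Hochberg adjusted p below 0.05, and 658 passed at an unadjusted p below 0.05. Liver had 169 such tissue-restricted transcripts, adrenal gland 118, left ventricle 102, cortex 82, hypothalamus 73 and outer medulla 36. By this rule a transcript about equally high in cortex and outer medulla could count for neither, which can lower their counts. With cortex and outer medulla averaged into 1 tissue, 643 transcripts were restricted in total. Of these, liver had 185, adrenal gland 127, left ventricle 107 and hypothalamus 76. A 5-fold rule on the mean, with no test, gave 173 in liver, 90 in adrenal gland, 81 in left ventricle, 42 in cortex, 54 in hypothalamus and 15 in outer medulla. Required in both columns, the same rule gave 103 in liver, 56 in adrenal gland, 64 in left ventricle, 21 in cortex, 24 in hypothalamus and 9 in outer medulla. Rescaling the tissues to the same median raised the count for hypothalamus to 186 and lowered that for outer medulla to 16. With a pseudocount of 0.01 the total was 308.

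**Figure D2:**
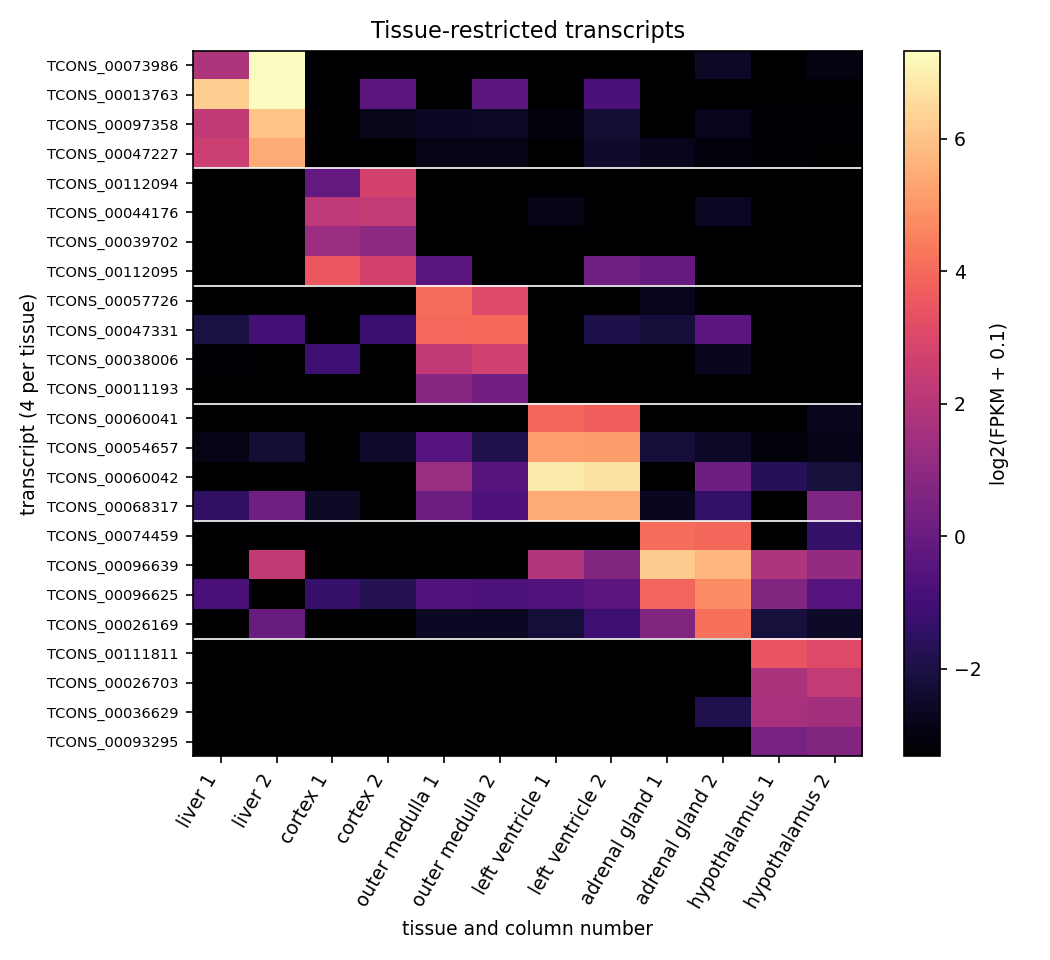
Colours show log2(FPKM + 0.1) of the 4 tissue-restricted transcripts with the largest ratio to the next tissue, for each of the 6 tissues (vertical axis, in blocks of 4), in all 12 columns (horizontal axis, tissue and column number). Each block is brightest in the 2 columns of its own tissue, as for TCONS_00060042 in left ventricle with 118 and 103.

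Liver-restricted lncRNAs had the largest contrasts, with a median of 12.8-fold over the next tissue on the FPKM + 0.1 scale. TCONS_00058886 (chromosome 2, 74647872 to 74659763) reached 543 and 1217 in liver against 4.43 and 10.4 in left ventricle, the next tissue (adjusted p = 1.2e-04, limma). TCONS_00073986 (chromosome 4, 30439033 to 30463937) had 3.46 and 156.5 in liver and was below 0.1 in all other columns (adjusted p = 0.0025). The small spread of those other columns enters that p. TCONS_00013763 (chromosome 1, 281545041 to 281548927) had 75.4 and 161, TCONS_00097358 (chromosome 7, 35373890 to 35608640) had 4.76 and 65.6, and TCONS_00047227 had 5.79 and 43.8. The last lies antisense to Akr1c12 (chromosome 17, 71324693 to 71393480), a gene of the aldo-keto reductase family. The 2 liver columns stood further apart than those of any other tissue, with 94 of 473 transcripts at FPKM 1 or more differing at least 4-fold. TCONS_00048236 (chromosome 18, 28103994 to 28139181), the third most abundant in liver on the mean, had 1.05 in column 1 and 1575 in column 2 and did not pass the test (adjusted p = 0.21).

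In the left ventricle, 102 transcripts were restricted and the median ratio to the next tissue was 10.2. TCONS_00060041 and TCONS_00060042 come from the same locus (chromosome 2, 173418576 to 173421499). The former had 15.4 and 13.2 in left ventricle and at most 0.052 elsewhere, and the latter had 118 and 103 against 2.30 and 0.6255 in outer medulla (adjusted p = 0.0011, limma). TCONS_00054657 (chromosome 2, 81839891 to 81843858) had 36.1 and 34.8, and TCONS_00068317 (chromosome 3, 142644461 to 142868604) had 43.2 and 43.8. The call for TCONS_00068317 was lost with a pseudocount of 0.01, though its mean was 50.9-fold over the next tissue on the FPKM + 0.1 scale.

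Cortex-restricted transcripts differed less from the next tissue, with a median ratio of 4.79. Outer medulla, the tissue most similar to cortex, counted among the other tissues in this ratio. TCONS_00044176 (chromosome 17, 439858 to 444279) had 4.41 and 4.996 in cortex and at most 0.063 elsewhere (adjusted p = 4.6e-06, limma). TCONS_00039702 (chromosome 16, 3945547 to 4391453) had 2.38 and 1.81 and was near 0 elsewhere, while the sum over its locus was 3.68 in cortex and 1.29 in outer medulla. TCONS_00112094 and TCONS_00112095 share a locus on chromosome X (116058963 to 116062369), with 0.799 and 6.66 for the former and 11.35 and 6.74 for the latter. The call for TCONS_00112095 (adjusted p = 0.028) was lost with a pseudocount of 0.01 and without any 1 of 7 columns: cortex 1 or 2, outer medulla 2, left ventricle 1, adrenal gland 2, and hypothalamus 1 or 2. In these fits its log2 ratio to the next tissue was 2.995 to 4.20, against 3.87 with all columns. In outer medulla, TCONS_00057726 (chromosome 2, 269129450 to 269162763) had 16.6 and 8.37 and was listed at 0 in 9 of the other 10 columns (adjusted p = 4.2e-06). TCONS_00057724 of the same locus, looked at after its values were seen, was present in all tissues, with 31.7 and 30.01 in cortex and 16.6 and 24.1 in outer medulla. TCONS_00047331 (chromosome 17, 75252975 to 75257907) had 15.9 and 16.1, TCONS_00038006 (chromosome 15, 30010515 to 30035706) had 4.85 and 6.34, and TCONS_00011193 (chromosome 1, 181397284 to 181398168) had 1.66 and 1.10. The call of restriction for TCONS_00047331 was lost with a pseudocount of 0.01, though its mean was 32.5-fold over the next tissue on the FPKM + 0.1 scale.

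Adrenal-restricted transcripts numbered 118, with a median ratio of 7.57 to the next tissue. TCONS_00074459 (chromosome 4, 61625469 to 61626957) had 17.0 and 15.04 in adrenal gland and at most 0.295 elsewhere (adjusted p = 4.6e-05, limma). TCONS_00096639 and TCONS_00096625 belong to 2 loci listed with the same interval on chromosome 7 (9865669 to 10274413), and the latter overlaps the zinc finger gene Zfp347. They had 72.7 and 52.7, and 14.7 and 26.9, in adrenal gland. TCONS_00026169 (chromosome 12, 38711799 to 38713881) had 1.49 and 17.65. The calls for TCONS_00026169 (adjusted p = 0.0298) and TCONS_00096639 (adjusted p = 0.0371) were lost without any 1 column of cortex, outer medulla, left ventricle or hypothalamus and without adrenal gland column 2. The former was also lost without liver column 1, and the latter without adrenal gland column 1, with no FPKM minimum and when the tissues were rescaled. The log2 ratio of TCONS_00026169 to the next tissue stayed at 4.11 without any 1 column of those 4 tissues and fell to 3.25 without liver column 1 and to 1.51 without adrenal gland column 2. That of TCONS_00096639 was 4.46, and 3.66 to 4.68 without any 1 column. With a pseudocount of 0.01 both calls and that for TCONS_00096625 were lost. Transcripts that were at FPKM 1 or more in adrenal gland and 5-fold above liver, cortex, outer medulla and left ventricle numbered 122. They stood at a median of 11.9% of their adrenal level in hypothalamus column 1 (quartiles 7.1 and 19%) and 5.5% in hypothalamus column 2.

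Hypothalamus-restricted transcripts numbered 73, with a median ratio of 6.24. TCONS_00111811 (chromosome X, 107512729 to 107513812) had 10.7 and 8.45 in hypothalamus and was listed at 0 in all 10 other columns (adjusted p = 1.2e-06, limma). TCONS_00026703 (chromosome 12, 52194506 to 52215839) had 3.18 and 5.04, and TCONS_00093295 (chromosome 6, 153309883 to 153312831) had 1.24 and 1.503. TCONS_00036629, which overlaps ENSRNOG00000050046 (chromosome 15, 51696840 to 51716150), had 3.004 and 2.67, against 0.175 in adrenal gland column 2. The 87 transcripts at FPKM 1 or more in hypothalamus and 5-fold above liver, cortex, outer medulla and left ventricle stood at a median of 3.6% of their hypothalamus level in adrenal gland column 1 and 21.0% in adrenal gland column 2 (quartiles 13.6 and 32.6%). Without adrenal gland column 2 and hypothalamus column 1, left out after the data were seen, 82 transcripts were restricted to hypothalamus and 97 to adrenal gland.

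Of the 142 transcripts detected in all tissues, 59 had a mean FPKM of 1 or more in each. Among these 59, TCONS_00012467 had the lowest tissue specificity index tau, 0.07 on a scale from 0 (even) to 1 (a single tissue). Tau on log2(FPKM + 1) is drawn towards 0 for very abundant transcripts. The means of TCONS_00012467 ran from 315.5 in hypothalamus to 1073 in adrenal gland. In ratio this range is wider than that of TCONS_00029281, with means from 4.878 in left ventricle to 8.305 in adrenal gland. TCONS_00029281 (chromosome 13, 87491609 to 87495679) ranged from 3.72 in left ventricle column 2 to 10.55 in liver column 1. TCONS_00021906, matching ENSRNOG00000047539 (chromosome 11, 31873796 to 31877080), ranged from 10.3 in hypothalamus to 22.0 in adrenal gland. TCONS_00051015, which shares a splice junction with NUDT21, a gene for an RNA 3′-end processing factor (chromosome 19, 11360457 to 11445119), ranged from 2.74 in liver to 6.30 in adrenal gland. Over the 1269 transcripts at FPKM 1 or more the median tau was 0.825, and 45.4% had a tau of 0.85 or more. The median tau was 0.85 for transcripts with no reference gene, 0.862 for those antisense to an exon, and 0.595 for those sharing a splice junction with one.

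The cortex and outer medulla libraries resembled each other most. Pearson's r across the 1812 detected transcripts, on log2(FPKM + 0.1), was 0.766 between them (Spearman's rho 0.734), against 0.622 for adrenal gland and hypothalamus (0.605), 0.448 for outer medulla and left ventricle, and 0.12 for cortex and hypothalamus. Transcripts are not independent replicates, so these values carry no p. Each of the 12 columns correlated best with the other column of its tissue, with r between 0.734 in liver and 0.888 in hypothalamus. The value for adrenal gland and hypothalamus was 0.473 without adrenal gland column 2 and hypothalamus column 1. It was 0.352 when each column was reduced by the median share of the other tissue given above. In limma tests of all 15 pairs of tissues, 125 of 604 transcripts (20.7%) differed between cortex and outer medulla at adjusted p below 0.05. In the other 14 pairs 57.1 to 76.8% of the tested transcripts differed, the largest share being between cortex and hypothalamus.

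**Figure D3:**
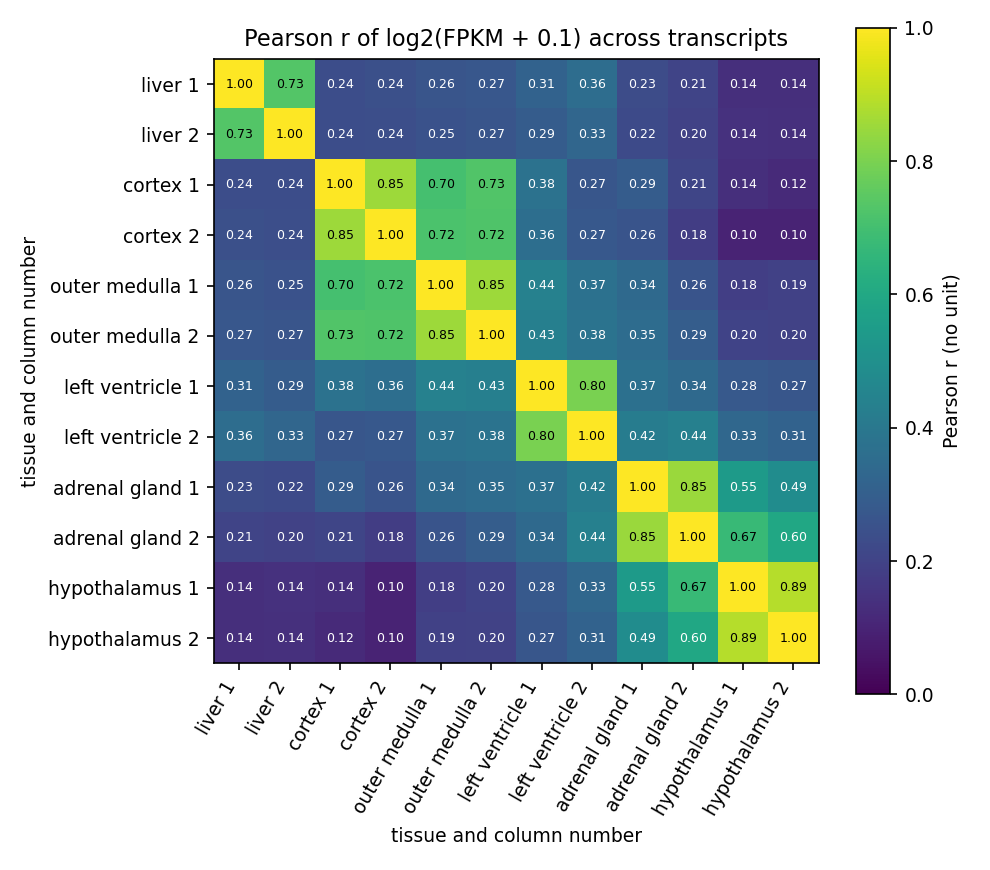
Pearson's r of log2(FPKM + 0.1) across the 1812 detected transcripts for each pair of the 12 columns, named on both axes by tissue and column number, with r printed in each cell. The cortex and outer medulla columns form a block with r of 0.705 to 0.854, and the adrenal gland and hypothalamus columns reach 0.487 to 0.672 with each other.

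Between outer medulla and cortex, 604 transcripts at FPKM 1 or more in either were tested with limma. There were 85 transcripts higher in cortex and 40 higher in outer medulla, and 201 differed at an unadjusted p below 0.05. The numbers depended on the pseudocount, with 33 higher in cortex and 9 in outer medulla at 0.01, and 158 and 83 at 1. TCONS_00012142, assigned to Mir675, a microRNA made from the H19 RNA (chromosome 1, 222639220 to 222642054), had 14.25 and 17.8 in cortex against 0.318 and 0.176 in outer medulla, a log2 difference of -5.56 (SE 0.52, adjusted p = 2.3e-04). TCONS_00107388, which shares a splice junction with the myosin light chain gene Myl1 (chromosome 9, 73349346 to 73369877), had 32.1 and 36.5 in cortex against 0.695 and 0.937 in outer medulla (log2 difference -5.24, SE 1.17, adjusted p = 0.015). It had 4.43 and 34.9 in left ventricle, a spread that enters this SE. Its call was lost without any single column of the 2 tissues and with a pseudocount of 0.01, while the log2 difference stayed between -5.43 and -5.05. TCONS_00044176 had 4.41 and 4.996 in cortex and was at or near 0 in outer medulla (adjusted p = 1.0e-05). TCONS_00043828 (chromosome 16, 72563691 to 72802225) had 2.25 and 6.36 in cortex and was listed at 0 in outer medulla (adjusted p = 0.0026). TCONS_00032703 had the largest log2 difference in this direction but was not called (adjusted p = 0.21), since its cortex columns read 3416 and 0.

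Among transcripts higher in outer medulla, TCONS_00057726 had 16.6 and 8.37 and was listed at 0 in both cortex columns (adjusted p = 1.0e-05, limma). The sum over its locus differed little, with 31.01 in cortex and 33.00 in outer medulla. TCONS_00047331 had 15.9 and 16.1 in outer medulla against 0 and 0.336 in cortex (log2 difference 6.27, SE 0.87, adjusted p = 0.0015). TCONS_00038006 had 4.85 and 6.34 against 0.372 and 0 (4.70, SE 0.63, adjusted p = 0.0014), while the sum over its locus was 165.49 in outer medulla and 155.70 in cortex. TCONS_00024834, a transcript of 9077 bases (chromosome 11, 76583571 to 76592959), had 2.97 and 3.13 against 0.334 and a value near 0 (3.92, SE 0.60, adjusted p = 0.0026). The outer medulla against cortex calls for TCONS_00038006 and TCONS_00024834 were lost with a pseudocount of 0.01, at which their log2 differences were 6.49 and 5.70. TCONS_00113045 (chromosome X, 36777265 to 36801371) had 19.6 and 4.62 against 0 and 1.57 and was not called (adjusted p = 0.39). Rescaling of tissues shifted outer medulla by -0.113 against cortex on the log2 scale. It gave 66 higher in cortex and 18 in outer medulla, or 97 and 27 when each column was rescaled. With tissues rescaled both counts fell, so the shift alone does not account for the change, whose cause was not tested. Without cortex column 2 the test called 55 and 22, and without outer medulla column 1 it called 26 higher in outer medulla.

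**Figure D4:**
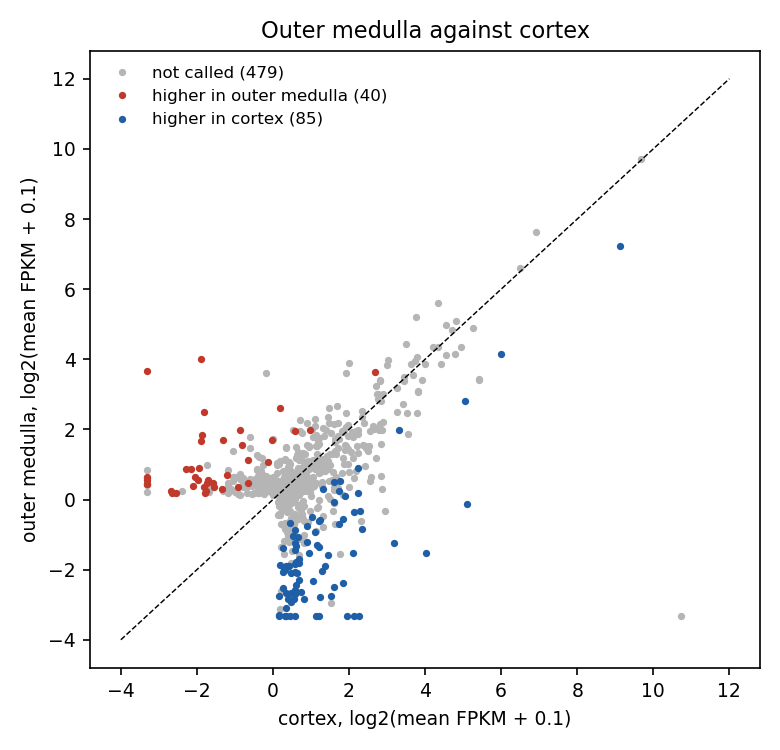
Each point is 1 of the 604 tested transcripts, placed by log2(mean FPKM + 0.1) in cortex (horizontal axis) and outer medulla (vertical axis), with the dashed line marking equal values. Transcripts called by limma at adjusted p below 0.05 are coloured, with 85 higher in cortex and 40 higher in outer medulla.

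The lncRNAs assigned to marker genes of each tissue, taken from lists fixed before the data were examined, were few. Of the 16 genes of the thick ascending limb and outer medulla, 3 had an assigned lncRNA: Irx2, a homeobox gene, Emx2, another homeobox gene, and Slc12a1, the sodium-potassium-chloride cotransporter of the thick limb. The median log2 ratio of outer medulla over the other 5 tissues was 2.84 for these 3 transcripts, at percentile 99.6 of 10000 random lists matched on mean expression. The transcript TCONS_00067610 at Slc12a1 had 36.5 and 36.6 in outer medulla and 12.2 and 14.7 in cortex. It was not called between these 2 tissues (log2 difference 1.44, SE 1.21, adjusted p = 0.47, limma), though the columns of each lay close together. Its columns in liver (0 and 1.319) and adrenal gland (1.501 and 0.146) stood further apart on the log2 scale, a spread that enters this SE. TCONS_00007547 at Irx2 had 2.06 and 1.92 in outer medulla against 1.06 and 1.42 in cortex (adjusted p = 0.58), and TCONS_00013941, antisense to Emx2, had means below 0.5 in every tissue and 0.41 or less in outer medulla against up to 0.52 in cortex. TCONS_00013938, from the locus of TCONS_00013941 but not a list member, was called higher in outer medulla (log2 difference of means 2.068). The sum over that locus was 0.94 in cortex and 1.69 in outer medulla. Adjusted over the list alone, 0 of the 2 tested members were called, as over all transcripts. Of the 31 hypothalamus genes, 2 had assigned lncRNAs, with 4 transcripts at Sox2, a transcription factor of neural stem cells, and 1 at Dlx6, a homeobox gene of GABAergic neurons. All 5 were highest in hypothalamus, with a median log2 ratio of 2.775 at percentile 99.9. The 4 at Sox2 are 1 locus and the random lists drew single transcripts, so this percentile counts 1 locus 4 times. TCONS_00055701 at Sox2 had 4.04 and 4.41 in hypothalamus, and 0 and 0.891 in adrenal gland (adjusted p of restriction 0.011, limma). It was the 1 member tested. The liver list found 1 transcript, at the fibrinogen gene Fga, TCONS_00056419, listed at 0 in liver and at 1.42 and 1.16 in adrenal gland. The list of endothelium and stroma found 1, antisense to Pdgfrb, a receptor of pericytes and fibroblasts, TCONS_00050203, with 6.404 and 3.02 in liver (adjusted p = 2.7e-04, limma). The lists for proximal tubule, left ventricle, adrenal gland, blood and immune cells, adipose tissue and pituitary found 0 transcripts. Of 48 known lncRNAs searched by symbol, Snhg11 was found as TCONS_00072731 (chromosome 3, 160733863 to 160743375), with 3.48 and 8.22 in hypothalamus and 2.76 and 2.23 in outer medulla, and it was not restricted (adjusted p = 0.64, limma). A search by symbol misses lncRNAs listed under another name. H19 was on the list, and TCONS_00012142 is assigned to Mir675, which is made from the H19 RNA.

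Neighbouring lncRNA loci tended to be highest in the same tissue. Among 146 pairs of adjacent loci with starts within 100 kb, 65.8% shared their highest tissue, against a mean of 17.9% and at most 30.1% over 10000 shuffles of the tissues over loci. Of the 10000 shuffles, 0 reached the observed share. In 56 of the 146 pairs the 2 loci were listed with the same interval. For 68 pairs at least 5 kb apart the share was 52.9%, against at most 39.7% over shuffles. Abundance and specificity were nearly unrelated across transcripts, with a Spearman's rho of -0.004 between tau and the highest FPKM. The sign turned with tau on linear FPKM (rho 0.156). Transcript length had a rho of -0.077 with the highest FPKM and -0.028 with tau.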

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

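Rescaling of columns, sums per locus, the use of the 5-fold and 4-fold rules beside limma, the block, the spread of outer medulla and cortex columns alone, the fit without hypothalamus and both treatments of the shares between adrenal gland and hypothalamus were chosen after seeing the data. For values that moved or turned, the cause was not tested, except where fewer transcripts or columns entered by construction. Over the main counts and values, 312 alternatives stayed within the spread or within 1.5 times, 115 moved further and 3 turned in sign. Of 678 alternatives for 34 named calls, 630 kept their side of the threshold, 47 lost it, 1 gained it and 0 turned. The numbers of detected transcripts in liver, cortex, outer medulla, left ventricle, adrenal gland and hypothalamus were 1159, 1367, 1367, 1182, 1247 and 1094 at FPKM 0.1, and 1731, 1912, 1995, 1836, 1958 and 1910 above 0. At FPKM 1 they were 473 in liver, 472 in cortex, 432 in outer medulla, 368 in left ventricle, 404 in adrenal gland and 243 in hypothalamus. Rescaling gave 762 (tissues) or 742 (columns) in hypothalamus. Detected in all tissues were 454 at FPKM 0.1 and 59 at 1. Without the most abundant transcript the next 10 held 52.47% in liver, 28.94% in outer medulla, 44.36% in left ventricle, 51.99% in adrenal gland and 53.98% in hypothalamus. Restricted transcripts numbered 308 with a pseudocount of 0.01 (cortex 28, outer medulla 8, adrenal gland 43, hypothalamus 32) and 240 by a 10-fold rule (cortex 16, outer medulla 6, left ventricle 53, adrenal gland 28, hypothalamus 9). A pseudocount of 1 gave 136 in cortex and 62 in outer medulla, and a 5-fold rule 42 and 15. Outer medulla had 16 with tissues and 23 with columns rescaled, and hypothalamus 186 and 181, or 177 with no minimum. Between outer medulla and cortex, 9 were higher in outer medulla and 33 in cortex with a pseudocount of 0.01, and 83 and 158 with 1, and 18 were higher in outer medulla with tissues rescaled. Tau and the percent at 0.85 or more were 0.8323 and 46.24 with no minimum, 0.8547 and 50.43 with outer medulla and cortex averaged, 0.8883 and 57.84 on linear FPKM, 0.7107 and 27.66 on shifted log2(FPKM + 0.1), 0.7992 and 42.59 per locus, 0.7983 and 41.41 without hypothalamus, 0.8325 and 46.72 less the shares, and 0.8352 and 46.79 without adrenal gland column 2 and hypothalamus column 1. The r of cortex and outer medulla was 0.746 and 0.7861 with pseudocounts of 0.01 and 1, 0.7837 with no minimum and 0.8074 per locus. The rho of tau with abundance turned to 0.1559 on linear FPKM. With no minimum, length had a rho of -0.1493 with abundance and -0.0574 with tau. Neighbours shared a tissue in 77.5% within 20 kb and 52.94% at least 5 kb apart. Leaving out 1 column at a time assumes that the lone column varies like the other tissues. It gave 22 to 48 higher in outer medulla (22 without cortex column 2, 26 without outer medulla column 1) and 55 to 95 higher in cortex (55 without cortex column 2). It also gave 57.35 to 60.91% for the top 10 in liver, tau of 0.8233 to 0.8305, 44.66 to 46% at 0.85 or more, and r of 0.722 to 0.7673. The rho of tau with abundance ran from -0.0149 to 0.0081, turning without liver column 1 (0.0036) and without cortex column 2 (0.0081). The rho of length ran from -0.1125 to -0.0713 with abundance and from -0.0438 to -0.0204 with tau. The column numbers did not pair the tissues, as deviations of the 15 pairs correlated at -0.059 to 0.122 with 1 above 0.1. With the number as a block, 578 were restricted, 38 and 82 differed between outer medulla and cortex, and a median of 438 differed per pair. Depth limits liver most, where column 2 had 3873000 implied fragments.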

Other observations

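The transcripts named here and the tests of counting error, of 1 share of the mean of both adrenal gland columns and of shared RNA as the whole cause were chosen only after the results were seen. Of 81 transcripts assigned to microRNA genes, 26 reached FPKM 1, and 7 of these were restricted by limma, 6 to hypothalamus and 1 to liver. Over all 1269 tested transcripts 580 (45.7%) were restricted, so restriction was not more common among those at microRNA genes. TCONS_00055335 at Mir124-2, a microRNA of neurons, had 1.85 and 1.31 in hypothalamus (adjusted p = 1.8e-04, limma). TCONS_00113683 at Mir384 had 4.71 and 5.28 (adjusted p = 9.3e-04), and TCONS_00113684 and TCONS_00113689 at Mir325, from the same locus (chromosome X, 77086036 to 77151776), had 2.71 and 2.83, and 3.56 and 3.94. TCONS_00003145 at Mir7a-2 had 1.88 and 2.12 in hypothalamus and 0.783 and 0.982 in adrenal gland. TCONS_00071227 at Mir129-2 had 1.12 and 1.01. The liver transcript was TCONS_00012142 at Mir675, with 39.2 and 100.3 in liver.

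Other restricted transcripts lay at named genes. In liver, TCONS_00047225, antisense to the aldo-keto reductase gene Akr1c19, had 42.3 and 137.4 (adjusted p = 9.9e-05, limma). TCONS_00008160, antisense to Slc27a5, an enzyme of bile acid conjugation, had 8.41 and 4.97, and TCONS_00032321, antisense to Afp, the fetal albumin relative, had 1.41 and 0.679. TCONS_00006231, which overlaps MBL2, a lectin secreted by liver, had 13.1 and 11.7. In adrenal gland, TCONS_00098844, which overlaps the steroid hydroxylase gene Cyp11b3, had 60.5 and 44.4 against 5.89 and 1.21 in hypothalamus (adjusted p = 0.0298). In left ventricle, TCONS_00040367, which overlaps Palld, an actin-binding protein gene, had 7.36 and 6.21 (adjusted p = 2.4e-05). In cortex, TCONS_00007426, antisense to the transcription factor gene Tcf21, had 0.789 and 1.26, and in outer medulla TCONS_00098119, antisense to the epithelial transcription factor gene Grhl2, had 3.175 and 3.23 (adjusted p = 0.046 for restriction, but 0.078 in the test against cortex alone). A further 13 transcripts at 11 loci stood within 2-fold in adrenal gland and hypothalamus and 5-fold above the other 4 tissues, and 5 of them lay on chromosome 6 between 142821642 and 143062780. Among these, TCONS_00090635 had 47.1 and 43.0 in adrenal gland and 44.2 and 52.4 in hypothalamus, TCONS_00090674 had 24.55 and 19.95, and 14.85 and 17.7, and TCONS_00090695 overlaps rno-mir-679, a microRNA of the imprinted Dlk1-Dio3 domain.

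The liver columns differed more than those of any other tissue. Counting error from the lower depth of column 2 was argued against, since among transcripts with at least 30 estimated fragments in both columns the SD of the log2 ratio was 1.501 in liver and at most 0.609 elsewhere. Reads of genes counted on the opposite strand in column 2 were also argued against, for antisense transcripts as a set. These differed from transcripts without a reference gene by -0.208 in median log2 ratio (95% bootstrap interval -0.427 to 0.096). A median cannot show such reads at a few transcripts, so reads of a few abundant genes stay open. A difference between animals or between pieces of liver stays open and was not tested.

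Adrenal gland resembled hypothalamus more than any other pair outside cortex and outer medulla, and RNA of each tissue in a library of the other is a candidate explanation. Among transcripts at 0.5 to 1 FPKM in the source tissue, the median share was 15.5% in adrenal gland column 2 (95% bootstrap interval 9.7 to 21.9) against 0.0% in column 1. It was 8.6% in hypothalamus column 1 (3.3 to 12.1) against 2.4% in column 2. Both differences lay in the direction predicted, but neither interval lay wholly inside or outside the range set beforehand. Such shares are near the limit of counting. With 1 kb of usable length, 3 fragments equal 0.223 and 0.171 FPKM in the adrenal gland columns, and 0.109 and 0.0942 in the hypothalamus columns. The 0.0% at 0.5 to 1 FPKM therefore need not be a lower share. At 3 FPKM or more, outside the prediction, 32 hypothalamus transcripts had a median share of 6.6% (1.6 to 14.4) in adrenal gland column 1. In column 2 it was 24.4% (18.5 to 34.1), so for these transcripts the share was lower in column 1. For 51 adrenal gland transcripts it was 13.2% (11.6 to 16.3) in hypothalamus column 1. In hypothalamus column 2 it was 7.8% (4.4 to 12.8), and these intervals overlap. At 1 share of the mean of both adrenal gland columns, 10.3% of 87 hypothalamus transcripts lay over 4-fold below the median share (4.8 to 18.7); this met the bound of 10% first written, but the binomial interval, added after the value was seen, spans it. After subtraction of the shares r was 0.352 (0.283 to 0.421), below the 0.447 of the highest other pair outside cortex and outer medulla, but subtraction lowers it by construction, and r without the columns with the larger shares, a condition added after the value of 0.352 was seen, was 0.473 against at most 0.45 for those other pairs. Mixed RNA and a likeness of the tissues themselves, which was not tested, therefore cannot be told apart as the source of the whole pattern.

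Fragments shared out differently among the transcripts of a locus could make a transcript differ between outer medulla and cortex while its locus did not. The locus sum was taken for 61 called transcripts at 47 loci with several listed transcripts. It kept a median of 95% of the log2 difference (95% bootstrap interval 85.0 to 102.4). This argues against such sharing among the listed transcripts, for these 61 calls as a set. Sharing with transcripts that the table does not list could not be seen, and calls at loci with 1 listed transcript were not tested. At 40 loci at least 50% was kept and at 3 loci under 25%. The latter include those of TCONS_00057726 (1.3%), the largest difference towards outer medulla, and TCONS_00038006 (2.0%), for which this stays open.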
